A study of Mus musculus with 18 samples.

How the data were processed

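The series holds whole-exome sequencing of genomic DNA from 17 leukemias of mice carrying both the NP23 (NUP98-PHF23) and the NHD13 (NUP98-HOXD13) transgenes, and of 1 tail sample of a wild-type C57Bl6-NIH mouse. Exons were captured with the SureSelectXT Mouse All Exon kit from a Nextera-type library, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, BWA 0.7.17 and GATK, with the builds mm10 and GRCm38, and give no role or order for them. MuTect2 is named in the labels, and the column names of the deposited table, per the file headers, are those of a comparison of each leukemia with a normal sample. The GATK version was not given in the sources used here.

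The rows of the deposited table analysed here number 2653, each a call in a leukemia against the wild-type tail, with a gene and consequence annotation. Every row analysed here had passed the caller's filter and lay in the bait regions, and no leukemia had the same site listed more than once. The read counts of the reference and alternative alleles and the total depth per call are whole-number counts deposited by the authors, without normalization. The allele fraction is a fraction estimated by the authors' caller, which can differ clearly from alternative reads over depth. A call in M18 had 5 of 106 reads (4.72%) but a fraction of 0.012. An Nsd1 insertion in M54 had 12 of 98 reads (12.2%) but a fraction of 0.174. Thresholds on allele fraction used the caller's value. The deposited strand-orientation fraction and the deposited tumor score (a log odds of the variant being real) were not used. The table holds 20 other columns of per-sample values, which were not used. Calls were made against 1 unmatched wild-type mouse, so variants that the transgenic colony inherited and that this mouse lacked are listed beside acquired ones. Its depth at the called sites ran from 7 to 3820 reads with a median of 43. Some rows may not be among those analysed here, so a count of 0 for a gene or list covers only these rows.

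A spreadsheet had turned 3 gene symbols into dates, and all 3 were restored from their RefSeq accession with the GRCm38.p6 gene table. Coding lengths, and exon numbers stored as dates, were read back from the cells by a fixed rule. Protein-altering calls were missense, stop gained, stop or start lost, frameshift, in-frame insertion or deletion, and essential splice site changes. A call at a site listed in no other leukemia is named private. Depth per leukemia was taken as the median depth at its sites shared by at least 10 leukemias on assembled chromosomes, and ran from 38 to 130 reads.

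Leukemias were grouped by the tissue in their labels, 11 from thymus and 6 from bone marrow, each from a separate mouse. Mouse numbers fall into a series with the ending NN (9 leukemias) and a series without it (8 leukemias, named plain here), which was treated as a possible batch. Values per leukemia were compared with an exact two-sided permutation test over all 12376 assignments, with Benjamini-Hochberg adjustment over 6 substitution classes. Genes with protein-altering calls in at least 3 leukemias were tested with the two-sided Fisher exact test, and pairs of gene lists with 3 to 14 leukemias hit likewise. Intervals are 95% Clopper-Pearson intervals and cover counting error only, since reads amplified by PCR are not independent molecules.

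The test of sites against coding length had been planned as a binomial test with lengths from a reference annotation, and was to be left out without one. No reference annotation with coding lengths was used here. In its place, chosen after the data were seen, the distinct protein-altering sites of each of 710 genes were set against a zero-truncated Poisson model with the coding length given in the deposited annotation. The rate was fitted by maximum likelihood at 0.109 sites per kb. Gene lists were likewise tested with the one-sided Fisher exact test of 847 distinct protein-altering sites against 462 distinct synonymous sites, which had been planned as an alternative, and the coding length version was not run. The 14 lists of leukemia genes and 6 comparison families were fixed before the data were examined, as were the groups, the tests and the first set of alternatives.

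On simulated data with 20000 genes, 200 had raised rates. The coding length test recovered 22% of these at a 10-fold rate, 90.5% at 50-fold and 99% at 200-fold, with 0 false calls. Simulated sites were drawn independently, while in the real calls neighbouring sites could be parts of the same insertion. The 0 false calls do not cover such clusters. The fitted rate was 1.31 times the true one at 10-fold and 6.36 times at 200-fold. The permutation test gave p under 0.05 in 6% of simulated comparisons with no effect, and in 97.4% with a shift of 2 SD. Shuffling protein-altering against synonymous labels 50 times gave 0 lists.

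Genes named in the text followed a fixed rule. It takes the 15 genes with the most leukemias among those with at least 2 distinct protein-altering sites, every member of a fixed list hit in at least 2 leukemias, up to 10 genes past the coding length test, and the 5 sites shared by the most leukemias. Not every gene and list is described in the text. Ties in the first part were settled by the p of the test actually run. Genes outside it are named as chosen after their values were seen. Alternatives left out shared sites, calls under a depth of 20 or 5 alternative reads, or calls under an allele fraction of 0.10, used medians, a single mouse number series, truncating or single-base calls, or each leukemia in turn left out. Alternatives added after the data were seen left out Nsd1, M31, M18 with M19 and M22, or database-marked sites, counted adjacent calls within 10 bases once in each leukemia or once over all leukemias, used the share of protein-coding genes for the lists (also without Nsd1 and without each leukemia), or left out each NN leukemia within that series. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.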

Results

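Exome sequencing was carried out on 17 leukemias that arose in mice transgenic for both NP23 and NHD13, fusions of the nucleoporin gene NUP98 with PHF23 and HOXD13. The series describes them as thymic acute myeloid leukemia. Samples came from the thymus in 11 mice and from the bone marrow in 6, and a tail sample of 1 wild-type mouse served as the normal for every call. The mouse numbers fell into the plain series (6 thymus and 2 bone marrow leukemias) and the NN series (5 thymus and 4 bone marrow). In all, 2653 calls at 2101 distinct sites were analysed, 2274 of them single-base changes and 379 insertions or deletions. Of the calls, 1051 altered a protein and fell in 720 genes. Median depth at widely shared sites was lowest in M21 (38 reads) and highest in M18 (130 reads). It averaged 71.7 ± 26.8 reads (SD, n = 11) in thymus and 74 ± 27.4 reads (SD, n = 6) in bone marrow leukemias. All coordinates are those of mm10 as the files give them.

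The question of which genes were mutated in more than 1 leukemia at different sites came first. Nsd1, which encodes a histone H3 lysine 36 methyltransferase, had protein-altering calls in 5 leukemias at 10 distinct sites, against 1.5 expected from its coding length of 8076 bases. It was the only gene past the coding length test (adjusted p = 4.1e-05, one-sided zero-truncated Poisson test with Benjamini-Hochberg adjustment over 710 genes), and 21 genes had a raw p under 0.05. Some of its calls were parts of 1 insertion: with sites within 10 bases counted as 1 location, Nsd1 had 7 locations (adjusted p = 0.00203) and Crb1 passed beside it. Adjusted over the list alone (11 genes of the fixed lists), 1 gene passed, again Nsd1. Cbl, a ubiquitin ligase that acts on receptor tyrosine kinases, was altered in M59 and M61. Kmt2b, a histone H3 lysine 4 methyltransferase, was altered in M21 and M22. In total, 40 genes had protein-altering calls in at least 2 leukemias and at 2 or more sites, and 6 of them in at least 3 leukemias. There were 24 such genes without M19, 9 without M18, M19 and M22, and 24 with adjacent sites as 1 location. With an allele fraction of at least 0.10, 3 genes were left: Nsd1, Cbl and Abcc2, the last chosen after its values were seen, with 1 of its 2 calls in M31.

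The Nsd1 calls were all insertions at the ends of exons. They were annotated as splice donor changes on chromosome 13 between 55261815 and 55310542, in M53, M54, M55, M58 and M59, all of the NN series (5 of 9 NN and 0 of 8 plain leukemias, Fisher exact p = 0.0294, two-sided). With neighbouring splice region calls there were 19 insertion calls at 8 exon ends. In M58 an insertion of 59 bases after coding base 6261, at position 55307042, was carried by 77 of 144 reads (53.5%, interval 45% to 61.8%), and the same insertion in M53 by 21 of 122 reads (17.2%, interval 11% to 25.1%). In M54 and M55 an insertion of 12 bases, identical to the start of the 59-base insertion, was called at this position in 12 of 98 and 5 of 95 reads. At position 55307044 these leukemias had further insertions of 43 and 20 bases, which matched later stretches of the 59-base insertion. The paired calls can therefore be parts of 1 longer insertion. M54 also had an insertion of 53 bases at position 55301844 in 17 of 110 reads. An insertion of 45 bases in M59 at position 55301845 matched a stretch of these 53 bases. The remaining M55 and M59 insertions had allele fractions of 0.034 to 0.078. A synonymous Nsd1 change, K1530K (position 55277621), was listed in 8 NN and 0 plain leukemias, at allele fractions of 0.039 to 0.794. Nsd1 was picked out for these positions after they were seen. Its insertions lay at 8 locations, all annotated in an intron within 4 bases of an exon. The same held for 7 of 177 locations of insertions in other genes (3.95%, interval 1.6% to 7.98%). Insertions inside an exon were counted as not near its end, however close they lay. Without M59, Nsd1 had 6 distinct sites and did not pass the coding length test (adjusted p = 0.165).

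**Figure D1:**
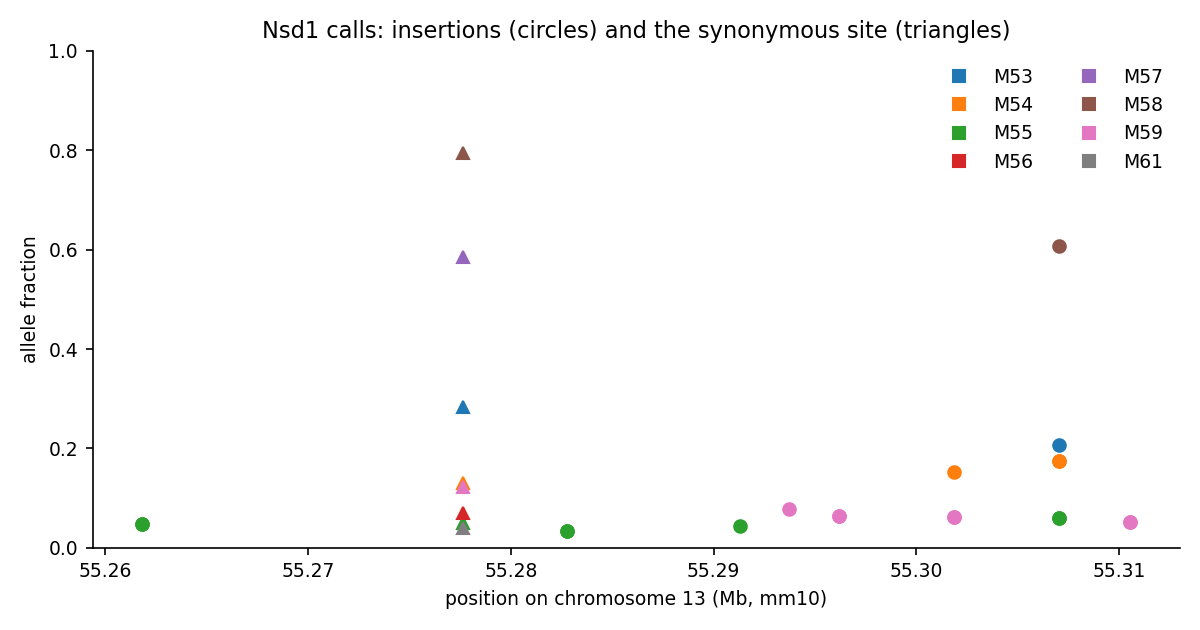
Allele fraction of each Nsd1 insertion call (circles) and of the synonymous K1530K call (triangles) against position on chromosome 13, colored by leukemia. M58 has the highest values, 0.608 for the insertion at 55307042 and 0.794 for K1530K.

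Cbl R557K (chromosome 9, position 44158779, exon 11 of 16) was carried by 53 of 125 reads in M59 (42.4%, interval 33.6% to 51.6%). In M61 a deletion of 29 bases across a Cbl splice acceptor (position 44164238, E364fs) was carried by 9 of 79 reads (11.4%, interval 5.34% to 20.5%). Kmt2b R1308C in M21 was carried by 5 of 30 reads (16.7%, interval 5.64% to 34.7%) and R2686H in M22 by 6 of 111 reads (5.41%, interval 2.01% to 11.4%). Pram1 was listed in 11 leukemias. Its rank rested on a site shared by all 11, P308S (chromosome 17, position 33641382), and its 1 further call, L537P in M31, had an allele fraction of 0.079.

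The other named genes carried mainly low-fraction calls. Ttn, which encodes titin, had 3 sites in M18, M22 and M24, and Muc4, a mucin gene, had 2 sites in M22, M56 and M61. Cpt1c, Fam214a, Hmgxb3, Ifna9 and Mroh2a were each called in 2 leukemias with allele fractions of at most 0.053. All calls of each of these genes lay within 10 bases of each other, at 1 location. In Gm4884, called in M21 and M31, the fractions were at most 0.047. Ceacam5, Dsel and Smg6 had 1 leukemia each with calls above 0.10, M21 for Ceacam5 (2 of 11 reads), M31 for Dsel and M55 for Smg6. The Smg6 changes I1215V and I1215K stood on adjacent bases, both in 47 of 106 reads.

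The fixed lists of leukemia genes were then compared with synonymous sites. In the RAS and receptor tyrosine kinase list, 3 sites in 2 leukemias altered Cbl and Ptpn11, against 0 synonymous sites (adjusted p = 1, one-sided Fisher exact test). Ptpn11 A72V, in the phosphatase SHP2 that signals toward RAS, was carried by 4 of 77 reads in M59 (5.19%, interval 1.43% to 12.8%), beside the Cbl change of the same leukemia. The list of other chromatin regulators had 16 protein-altering sites in 6 genes and 10 leukemias (58.8%, interval 32.9% to 81.6%) against 6 synonymous sites (adjusted p = 1), and 10 of the 16 sites were the Nsd1 insertions. Without Nsd1 the list had 6 protein-altering and 5 synonymous sites, and 5 leukemias were hit (29.4%, interval 10.3% to 56%). The other sites were Kmt2a T1311I in M31 (6 of 22 reads), both Kmt2b changes, a Kmt2c insertion in M23, Kmt2d A5487T and Ncor1 P1203S in M19, the last 3 at allele fractions of 0.043 or less. In the DNA methylation list, Tet2 and Tet3, which encode enzymes that oxidise 5-methylcytosine, had 3 frameshift calls in M18, each in 5 reads. M18 had 223 private calls below an allele fraction of 0.10, the most of the 17 leukemias. Nup210 L425F in M57, a database-marked call on chromosome 6 with an allele fraction of 0.051, was the only protein-altering change in the nucleoporin list, and it lay among 17 database-marked calls of M57 on that chromosome, whose median allele fraction was 0.05. The rows analysed here held 0 protein-altering sites in the remaining 10 lists, among them JAK-STAT and cytokine receptor, BCOR-PRC1, PRC2 with ASXL and PHF6, hematopoietic transcription factors, NOTCH, cohesin, RNA splicing, and HOX with MEIS partners. For each of these, 0 of 17 leukemias allows a share of up to 19.5% (upper Clopper-Pearson bound), for the rows analysed here only.

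No list of leukemia genes passed the test, at adjusted or raw p under 0.05. Adjusted over the list alone (the 14 lists), 0 passed. For most lists the test could not decide, since the 10 lists with 0 protein-altering sites could not pass. RAS and DNA methylation, each with 3 sites against 0 synonymous ones, had a raw p of 0.271 (one-sided Fisher exact test), the smallest that 3 sites can give. Only other chromatin regulators held more sites. Against the share of protein-coding genes in place of synonymous sites, an alternative added after the data were seen that takes no account of coding length, other chromatin regulators (adjusted p = 1.98e-13), DNA methylation (adjusted p = 0.0261) and 1 comparison family passed. Without Nsd1 the adjusted p for other chromatin regulators was 0.00463, and without M18, which held all 3 DNA methylation calls, that for DNA methylation was 1. Of the 6 comparison families, olfactory and vomeronasal receptors passed against synonymous sites, with 39 protein-altering and 6 synonymous sites (adjusted p = 0.0152), and this ended when M22 or M31 was left out (without M31, raw p = 0.0994), with the depth filter, at an allele fraction of at least 0.10, and without database-marked sites. Keratins had 7 and 2 sites, Zfp genes 10 and 5, mucins 2 and 1, and major histocompatibility genes 2 and 0, each with adjusted p = 1, and 1 further family is not described here. Among 15 pairs of lists, 0 passed at adjusted p under 0.05 and 1 at raw p under 0.05. That pair had an adjusted p of 0.0945.

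Numbers of calls were compared between thymus and bone marrow. Thymus leukemias had 192.5 ± 247.3 calls (SD, n = 11) and bone marrow leukemias 89.2 ± 30.4 (SD, n = 6), a difference of 103 within the spread between leukemias (p = 0.389, exact permutation test). Protein-altering calls numbered 73.6 ± 69.3 (SD, n = 11) and 40.2 ± 20 (SD, n = 6) (p = 0.255, exact permutation test). M31 had 885 calls, followed by M18 with 280, M19 with 257 and M22 with 251, all from thymus and all of the plain series. The medians lay the other way, at 68 calls in thymus and 89 in bone marrow. Without M31 the difference of the means was 34.1 calls. Within the NN series the thymus mean of all calls was 59.6 ± 7.77 (SD, n = 5) and the bone marrow mean 74 ± 18.4 (SD, n = 4) (exact permutation p = 0.183), and within the plain series the means were 303.3 and 119.5 (exact permutation p = 0.464). Within the NN series the thymus mean of protein-altering calls, 20.2 ± 1.64 (SD, n = 5), lay below the bone marrow mean of 29.2 ± 9.54 (SD, n = 4) (exact permutation p = 0.0317). This difference of -9.05 shrank to -4.47 without M59, which had 43 protein-altering calls (exact permutation p = 0.0714), and leaving out any of 8 of the 9 leukemias, M60 excepted, gave p above 0.05. Within the plain series, where 28 assignments allow no p under 0.0357, the means were 118.2 ± 66.2 (SD, n = 6) and 62 ± 17 (SD, n = 2) (exact permutation p = 0.429). The difference between the series in this contrast was itself within chance (p = 0.315, exact permutation test over 3528 assignments).

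**Figure D2:**
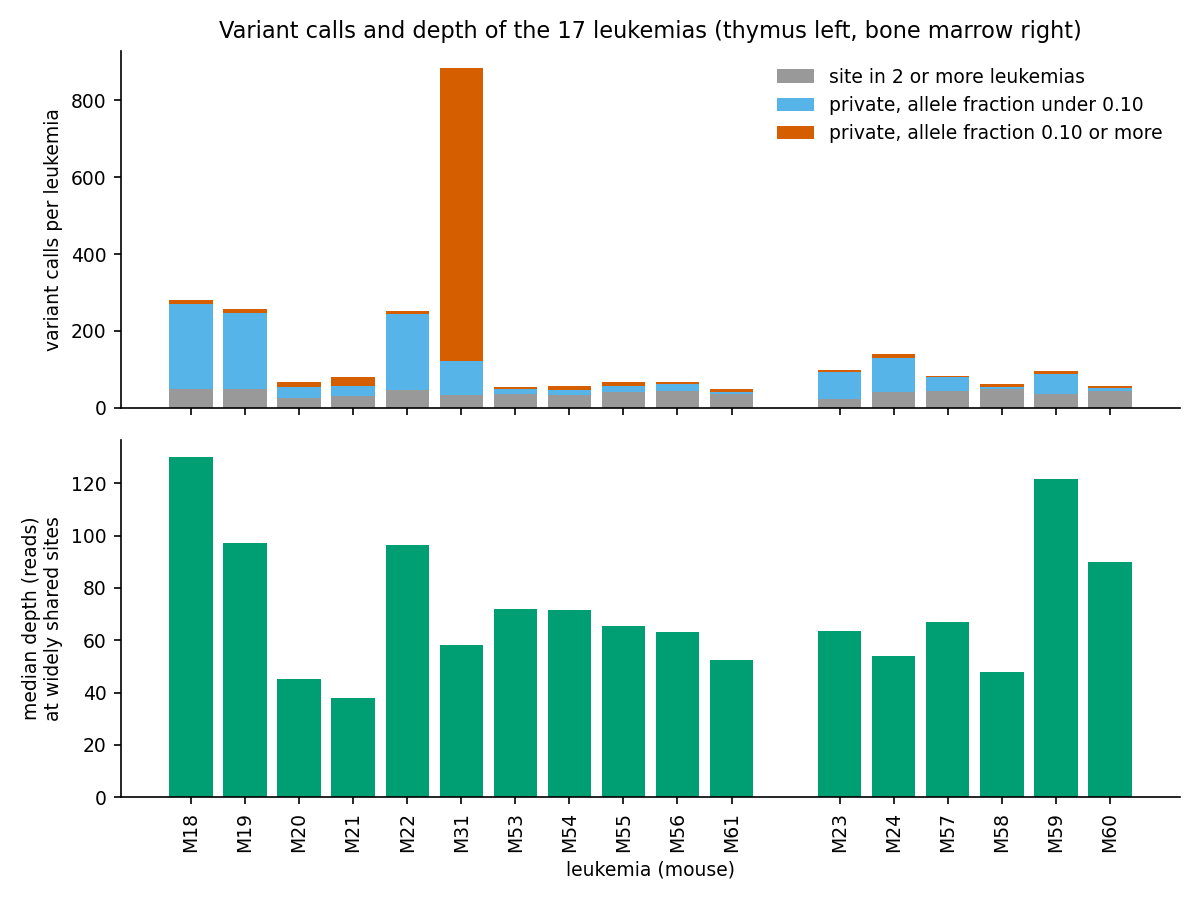
Variant calls per leukemia, split by site sharing and allele fraction (upper bars), and median depth in reads at widely shared sites (lower bars), with thymus leukemias left and bone marrow right. M31 stands apart with 763 private calls at an allele fraction of 0.10 or more, while the private calls of M18, M19 and M22 lie mainly below 0.10.

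Of the 885 calls of M31, 607 were marked as database variants, against 1 to 22 in each of the other leukemias. Of these 607, 583 lay in tracts, which also held unmarked calls. The tracts were drawn from the marked calls themselves, as runs without wide gaps, so this number follows partly from how they were drawn. On chromosome 1, 437 calls, 359 of them marked, fell between 93304940 and 165564000, with a median allele fraction of 0.31. On chromosome 19, 43 calls (35 marked) fell between 20379615 and 27333653 and 207 (176 marked) between 38053211 and 58822112. On chromosome 7, 26 calls (13 marked) fell between 36769679 and 41745628. These tracts held 117 of the 179 protein-altering calls of M31, including all 5 in Crb1, a cell polarity gene, which had an adjusted p of 0.111 in the coding length test. The chromosome 19 tract from 38053211 opened with a call of allele fraction 0.028, and the chromosome 7 tract closed with a call of 0.065.

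**Figure D3:**
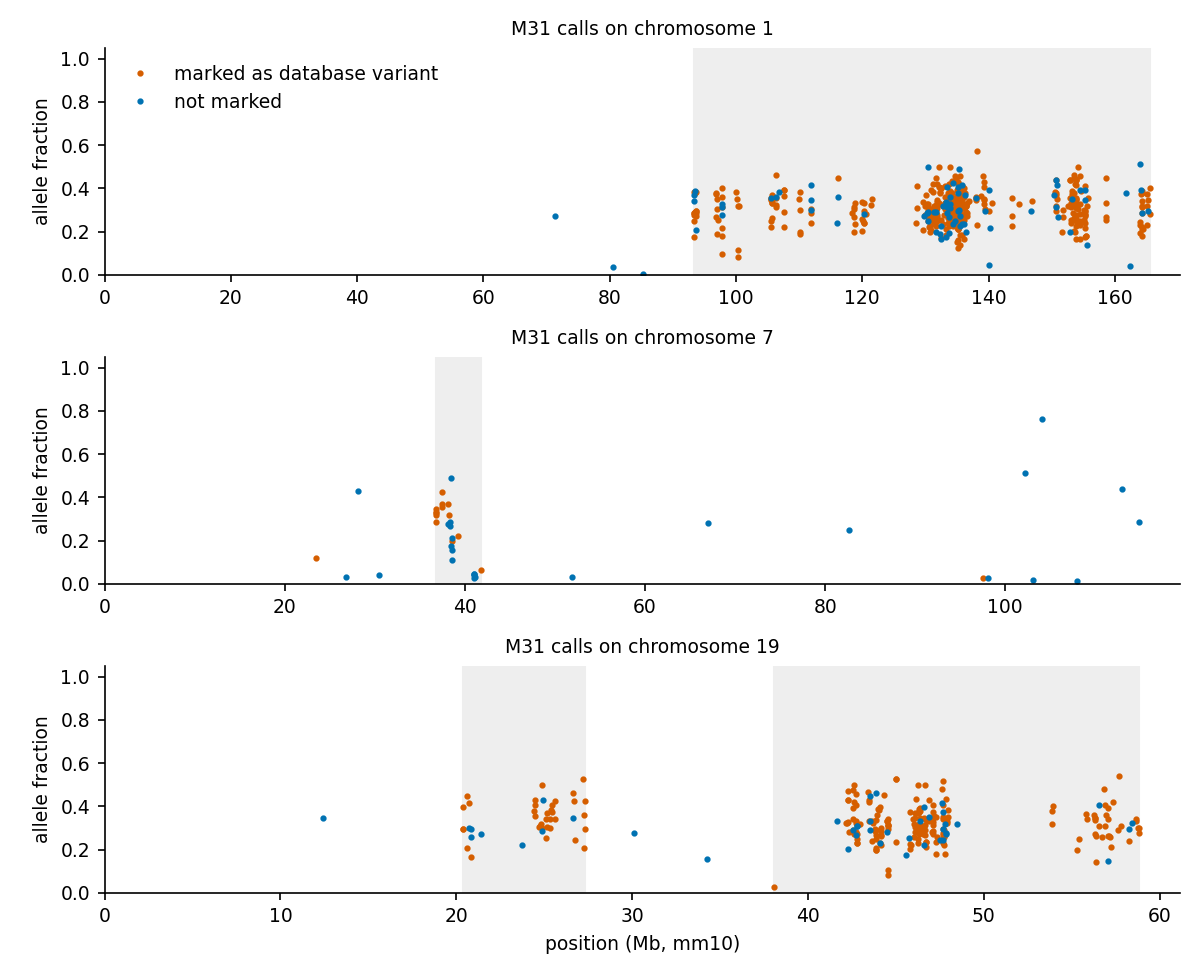
Allele fraction of each M31 call against position on chromosomes 1, 7 and 19, orange where marked as a database variant and blue where not, with the tracts shaded. The tract on chromosome 1 holds 437 calls with a median allele fraction of 0.31.

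No gene passed the test between the tissues. Of 28 genes with protein-altering calls in at least 3 leukemias, 0 passed at adjusted or raw p under 0.05 (two-sided Fisher exact test). Only 6 of the 28 had 2 or more distinct sites. The others were tested on 1 site shared between leukemias, as with Zcchc4 A170S, so the test mostly compared shared sites. Adjusted over the list alone, which held only Nsd1, 0 passed. Nsd1 was called in 3 thymus and 2 bone marrow leukemias (p = 1). In the substitution spectrum, C>T made up 52.5 ± 11.2% of single-base calls in thymus and 52.1 ± 14.4% in bone marrow (SD, n = 11 and 6, adjusted p = 0.944, exact permutation test), and 0 of 6 classes passed, at adjusted or raw p under 0.05. Within each series C>T was lower in thymus, with a thymus minus bone marrow difference of -6.72 percentage points in the plain series (exact permutation p = 0.321) and -1.41 in the NN series (exact permutation p = 0.81). C>A accounted for 13.1 ± 3.81% and 15.6 ± 11.8%, the latter including M59 at 39%. The median allele fraction per leukemia averaged 0.193 ± 0.129 in thymus and 0.129 ± 0.107 in bone marrow (SD, n = 11 and 6, p = 0.316, exact permutation test). Without M18, M19 and M22 the difference was 0.124 (p = 0.0436, exact permutation test), an alternative added after the data were seen. These thymus leukemias were picked for their low-fraction calls and had the lowest medians (0.031, 0.033 and 0.032). Leaving them out was bound to raise the thymus mean, so this p decides nothing. Within the plain series these means were 0.116 and 0.05 (exact permutation p = 0.643), and within the NN series 0.284 and 0.169 (exact permutation p = 0.127).

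Sites listed in several leukemias were set apart from private ones. Of the 2101 sites, 1990 were listed in 1 leukemia and 111 in 2 or more, and 27 were listed in at least 10. An intronic Perp site (chromosome 10, position 18853702) and an intronic LOC101056073 site (chromosome 4, position 145513052) were listed in all 17 leukemias, at median allele fractions of 0.49 and 0.226. A site between Olfr1507 and Dad1 (chromosome 14, position 53717147) and a site in the noncoding transcript LOC100041034 on an unplaced scaffold of chromosome 1 (position 152486) were listed in 16. Zcchc4 A170S (chromosome 5, position 52796158) was listed in 15 leukemias at a median allele fraction of 0.5. Ddx42 D78E and 4931431F19Rik Q434R were also listed in 15, at median allele fractions of 0.488 and 0.95. Of the shared sites, 34 were listed only in plain and 26 only in NN leukemias, and 6 differed between the series (adjusted p under the threshold of 0.05, Fisher exact test). Gcgr V148M, in the glucagon receptor, was listed in 7 of 8 plain and 0 of 9 NN leukemias, and Ankrd13a A313T in 0 plain and 8 NN leukemias (both p = 0.000411, adjusted p = 0.0152, Fisher exact test).

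Private protein-altering calls with an allele fraction of at least 0.10 and a depth of at least 20 reads numbered 187, of which M31 held 132 and 14 other leukemias 55. The genes in this paragraph were chosen after their values were seen. M59 carried Gab1 D685G, in an adaptor of receptor tyrosine kinase signalling, in 44 of 125 reads (35.2%, interval 26.9% to 44.2%) and a frameshift in the adaptor gene Nck2 in 9 of 46 reads (19.6%, interval 9.36% to 33.9%), beside its Cbl and Ptpn11 changes. In M19, Brpf1, a subunit of histone acetyltransferase complexes, had E827K in 38 of 80 reads (47.5%, interval 36.2% to 59%). M22 had a frameshift in Lrba in 29 of 71 reads (40.8%, interval 29.3% to 53.2%). M61 had V132E in Tigit, an inhibitory receptor of T and NK cells, in 23 of 43 reads (53.5%, interval 37.7% to 68.8%). Of the 55 calls outside M31, 12 were truncating. Without a matched normal, inherited and acquired changes were not separated among these calls.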

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

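Dixon's test and the count of splits were fixed beforehand, and every other test in this part was chosen only after its result was seen. Chance alone picks out about 1 in 20 groups with Dixon's test.

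The C>A share of M59, 39% of its single-base calls, lay far from the other bone marrow leukemias by Dixon's test. In 1 further bone marrow leukemia, M57, 17 database-marked calls lay on chromosome 6 between 88586904 and 135152963 at a median allele fraction of 0.05. A synonymous Nup98 change, G450G (chromosome 7, position 102169472), was listed in 9 leukemias at allele fractions of 0.513 to 0.844, with 0 of 20 reads in the wild-type tail. Insertions in the 5 prime UTR of Vav1, whose promoter is used to drive transgenes in blood cells, were listed in 3 leukemias, M18, M21 and M22 (chromosome 17, position 57279190), with different lengths in each and at allele fractions of 0.303 to 0.5.

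Database-marked calls numbered 607 in M31, far above the 1 to 22 of the others. Of these 607, 583 lay in the tracts on chromosomes 1, 7 and 19, which were drawn from these same calls. A first test, on shared sites at 0.9 or more elsewhere, had 1 site and was replaced by sites at 0.4 to 0.6 in the other leukemias. At 21 such sites outside the tracts the M31 median was 0.317, below the medians of every other leukemia (0.431 to 0.5535), which is consistent with DNA of a second mouse mixed into the M31 library. Heterozygous tracts in every M31 cell with poorer mapping would leave those sites alone, and the upper quartile of 0.394 argues against that. The median in the tracts was 0.311, beside 0.317 at those sites. The test therefore bears on the shift alone and does not tell whether the tracts belong to M31 or to another mouse. No biological explanation was tested, and a copy number change at the 21 sites stays open.

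The synonymous Nsd1 change was listed in 8 leukemias, all of the NN series, which argues against a chance fall on the mouse number series (Fisher exact p = 0.000411, two-sided, adjusted p = 0.0152 over the 111 shared sites). In 6 of these 8 the whole interval of the share of variant reads lay below 50%, which argues against an inherited variant of the mouse's own gene in every cell with both copies kept. The insertions were annotated in an intron within 4 bases of an exon at 8 of 8 locations, against 7 of 177 in other genes (3.95%). Insertions inside an exon counted as not near, so distance to an exon end from that side was not measured. The Fisher exact p was 3.81e-08 once multiplied by the 173 genes with insertions, as Nsd1 was picked for this. This argues against mutations falling on the intron side of exon ends as often as in other genes, while changes selected for lying there stay open. After coding base 6261, M53 and M58 carried the same 59 inserted bases, and those of M54 and M55 matched parts of them. Whether the inserted bases are those of the next Nsd1 exon was not tested. Reads from a spliced copy of Nsd1 may be the source: at the synonymous site the allele fraction rose with relative depth (Pearson r = 0.895, permutation p = 0.0145, adjusted p = 0.029 over 6 relations, n = 8; Spearman rho = 0.333, permutation p = 0.428), but this rests on M57 and M58, since r without them was -0.409, and M56, M57 and M61 had the site with 0 listed insertions. In M57 and M58 depth was 2.66 and 4.92 times the median with other-allele reads at 1.1 and 1 times it, which a gain of the variant allele would also give, the site is database-marked, and the source of any extra copy was not tested.

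In M18, M19 and M22, 618 private calls lay below an allele fraction of 0.10. Over all 17 leukemias such calls rose with median depth (Pearson r = 0.623, permutation p = 0.00957, adjusted p = 0.0287 over 6 relations; Spearman rho = 0.404, permutation p = 0.108; r without the 2 farthest = 0.584), in the plain series with r = 0.96 (permutation p = 0.000471, adjusted p = 0.00283, rho = 0.905, r without 2 = 0.963, n = 8) and in the NN series with r = 0.724 (permutation p = 0.0414, adjusted p = 0.0621, rho = 0.483, r without 2 = 0.517, n = 9). M18, M19 and M22 were picked for such calls, and over the 14 others r was 0.0228 (permutation p = 0.94), with 51 such calls in M59 at a depth of 121.5 reads against 198 in M19 at 97, so depth as their source stays open. C>A made up 8.55% of the single-base calls among the 618 (interval 6.15% to 11.5%), which argues against oxidised guanine. C>T made up 70.2% of them (interval 65.7% to 74.3%), and what gave this share was not tested. Of the 618, 1.46% were database-marked (interval 0.668% to 2.75%), which argues against DNA of another strain, and 26.2% were insertions or deletions. Real low-fraction changes of the leukemias were not tested and stay open.

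For genes that differ between thymus and bone marrow, the real split gave 0 at raw p under 0.05. With 0 in the real split, all 100 of the 100 splits must give at least as many (the highest of the others gave 5). This count therefore decides nothing.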

How the results depend on the processing

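Choices added after the data were seen left out M31, or M18 with M19 and M22, or database-marked sites, or Nsd1, counted adjacent calls once per leukemia or adjacent sites as 1 location, or used the share of protein-coding genes (also without Nsd1 and without each leukemia), or left out each NN leukemia within that series. The cause of the changes below was not tested unless fewer calls or leukemias make it plain. Thymus minus bone marrow turned to -21 for calls and -8 for protein-altering calls with medians, and to -14.4 and -9.05 within the NN series. Leaving out each leukemia gave 34.1 (without M31) to 118 for calls and 22.9 to 40.2 for protein-altering calls, and within the NN series -11.8 (without M60) to -4.47 (without M59, exact permutation p = 0.0714) for protein-altering calls. No substitution class passed under any alternative, but signs turned: without shared sites T>C to -2.23 and T>G to -0.451; with the depth filter C>T to -1.72 and T>G to -0.932; at an allele fraction of 0.10 C>A to 3.53, C>G to -1.6, C>T to -3.8, T>A to -0.812 and T>G to -0.968; without M31 T>C to -0.849; without M18, M19 and M22 C>T to -4.24. Without those 3, thymus leukemias picked for their low-fraction calls, the allele fraction difference was 0.124 (exact permutation p = 0.0436, which that choice favours). Recurrent genes numbered 10 with the depth filter, 3 at an allele fraction of 0.10, 4 truncating, 6 in at least 3 leukemias, 9 without M18, M19 and M22, 24 with adjacent sites as 1 location, and 24 (without M19) to 40 with each leukemia left out. The coding length test gave 2 genes, Nsd1 and Crb1, with the depth filter, without M18, M19 and M22, or with adjacent calls or sites counted once, 0 at an allele fraction of 0.10 or without Nsd1, and 0 (without M59) to 1 with each left out. With single-base calls its 1 gene was Crb1. Nsd1 sites numbered 6 without M59 and 3 at an allele fraction of 0.10. Gene lists numbered 0 with the depth filter, at an allele fraction of 0.10 or without database-marked sites, 3 with the share of protein-coding genes (DNA methylation, other chromatin regulators and 1 comparison family; 3 also without Nsd1 or any leukemia but M18, and 2 without M18), and 0 (without M22 or M31) to 1 with each left out. Shared sites numbered 65 at an allele fraction of 0.10. Genes differing between tissues stayed at 0 in all 8 alternatives run. For co-occurrence no alternative had been fixed beforehand, and the coding length version of the gene lists was not run.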

Other observations

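The values in this part were chosen only after they were seen. Phf23, the mouse counterpart of the gene in the NP23 fusion, carried synonymous changes as Nup98 did. T126T and L127L, on adjacent bases of chromosome 11 (positions 69998519 and 69998520), were listed in 4 NN leukemias, M55, M57, M58 and M61, at allele fractions of 0.371 to 0.515. D323D (position 69999110) was listed in 7 leukemias, 3 plain and 4 NN, at allele fractions of 0.068 to 0.447. The wild-type tail had 0 alternative reads at all 3 sites. At Nup98 G450G the depth was 137 to 380 reads, higher in each leukemia than its median depth at widely shared sites (48 to 130 reads). At Phf23 T126T it was 99 to 151 reads, against medians of 48 to 67. At D323D the depth was higher too, except in M18 (121 reads against 130). The deposited calls do not say which of the transgene and the mouse gene the reads came from. That and the reason for the raised depth were not tested.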
